A study of Homo sapiens with 6 samples.

How the data were processed

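RNA was measured in 6 libraries of H460 cells, 3 from cells kept for 24 h without glutamine and 3 from glutamine-replete cells. Per the labels, RNA was extracted with TRIzol, and 500 ng of total RNA entered a Lexogen QuantSeq 3′ mRNA library. The submitters' processing notes name Bowtie2, edgeR and the genome build hg19 without a role or version for each. The deposited files hold raw counts per gene symbol, with 1 library per file. The unit was checked on the values, which were whole numbers with a different total in each library. The counting program, its use of strand and the annotation are not stated in the sources used here. No positions are given for genes, because the GENCODE 29 annotation on GRCh38 used here differs in build from the counted data. It served only for gene names, overlaps between genes and transcript features.

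Each file held 25737 entries for 24462 distinct symbols. Counts of the 286 symbols on several entries (1561 entries) were summed, a choice made after seeing the files. Of all counts, 0.092% lay outside the largest entry of such a symbol. In current name tables, 21922 symbols were current, 1461 were older names and 1079 had no match. Totals ran from 7550849 to 10914899 counts per library, and 3 counts, the limit for a count of 0, stood for 0.275 to 0.397 CPM.

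Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by trimmed-mean (TMM) factors and tested between the 2 groups with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The Benjamini-Hochberg adjusted p threshold was 0.05, and tests were two-sided. CPM in the text uses library totals, whereas log2 fold changes use the TMM factors, which ran from 0.917 to 0.929 in depleted and from 1.08 to 1.09 in replete libraries. Gene lists of at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Of 32 lists, 30 were tested and 29 are described here. The blood cell marker list had too few tested members, and mitochondrially encoded genes were not analysed here. For genes with 0 counts in a group, the fold change is a lower bound against 3 counts over the group. For genes with few counts, the ratio has an exact 95% counting interval.

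The rule for named genes took the 6 largest changes in each direction among genes with an adjusted p under 0.05, a mean CPM of at least 10 and no overlap between groups. It also took the 3 members with the smallest p in each direction of each list that camera called or that the design asked about, and 11 genes in any case, which gave 118 genes, not all of which are described here. Exceptions named after their values were seen are the cell type markers and the members of families in the closing section. Of the 118 genes, 115 were found in the annotation, and 15 had exons that overlap another counted gene, in each case on the opposite strand.

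The alternatives were DESeq2 size factors, library totals alone, upper quartile factors, no count filter, a mean CPM of at least 10, a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, glmTreat against 1.5-fold, and, for lists, an estimated correlation, fry and cameraPR. Using the largest entry per symbol and removing a per-library loess trend (span 0.5) over transcript GC content and length were added after seeing the data. The test was also tested on simulated counts with the same library totals, in which 12296 genes passed the filter. It recovered 86.7% of 98 genes planted at a log2 change of 1 and 100% of 93 at 2, with 11 false calls of 189 (5.82%). Because few genes were planted, this does not show the false call rate or the scaling where most genes change, as in the real data. Of 29 lists tested there, the 1 with a planted shift was called and 0 of the others were. Genes were drawn independently, so this could not test the preset correlation. Permutations and tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.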

Results

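H460 is an established human lung cancer cell line of large-cell origin with a mutated KEAP1 gene. The series compared H460 cells kept without glutamine for 24 h (depleted, 3 libraries) with glutamine-replete H460 cells (3 libraries) by 3′-end mRNA sequencing, in which reads come from near the polyadenylated end of each transcript. The depleted libraries held 10914899, 8730445 and 8667798 counts, and the replete libraries held 9028230, 7918265 and 7550849. Between 15963 and 16637 gene symbols had at least 1 count in a library. A level of 3 counts, the limit that a count of 0 allows, corresponded to 0.275 to 0.397 CPM (counts scaled to a common library total) per library, and this limit and all counting intervals cover counting error only. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom from 1.51 to 3.97 for all pairs except those with depleted replicate 2, so no library was counted as a duplicate. Depleted replicate 2 stood apart, at 19.75 against depleted replicate 1 and 11.77 against depleted replicate 3. The first principal component of log2 CPM held 92.1% of the variance and separated the 2 groups, and the second held 3.80% and set depleted replicate 2 apart from the other libraries. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels describe dialyzed serum for the depletion medium and do not spell out the serum of the replete cells over the same hours.

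The first question was which transcripts differed after a day without glutamine. Glutamine withdrawal was accompanied by a change in most of the measured transcriptome: of 12739 genes tested, 10012 (78.6%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4987 of them higher and 5025 lower in the depleted cells. Of these, 2772 rose and 3017 fell by more than 2-fold, and 442 rose and 407 fell by more than 8-fold. The CPM ranges of both groups did not overlap for 10314 genes (81.0%), where chance gives 10%. The largest increases were in genes with almost no counts in replete cells. ALOXE3, a lipoxygenase-family enzyme of the skin barrier, reached 37.9 ± 6.06 CPM (mean ± SD, n = 3) in depleted cells and had no count in replete cells, so it was at least 310.3-fold higher against a floor of 3 counts over the group. CYP1A1, the cytochrome P450 best known as a target of the aryl hydrocarbon receptor, reached 34.8 ± 3.78 CPM against 1 count over the replete libraries, a ratio of 860.0 with a 95% counting interval of 154 to 34003. IL24, a cytokine of the IL-10 family, reached 52.0 ± 6.21 CPM against 3 counts, a ratio of 423 (145 to 2055). FCMR, a receptor for IgM, reached 97.0 ± 11.2 CPM against 4 counts, a ratio of 593 (231 to 2177). IL24 and FCMR end next to each other on opposite strands in the GENCODE 29 annotation, and the counting is not stated to use strand, so reads of this pair may have been shared. The remaining genes of this set of 6 were the loci LOC100505715, at a ratio of 1020.1 (183 to 40326) over 1 count, and LOC284581, at a ratio of 491 (168 to 2383) over 3 counts.

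The largest decreases were in genes that were well measured in replete cells. FAM20C, a Golgi kinase that phosphorylates secreted proteins, fell from 57.9 ± 3.74 to 0.880 ± 0.0627 CPM, a log2 fold change of −5.79 (SE 0.16, edgeR adjusted p = 7.13e-12). ANXA6, a calcium-dependent membrane-binding annexin, fell by 5.40 on the log2 scale (edgeR adjusted p = 1.44e-11). NEURL1B, a ubiquitin ligase of Notch ligand trafficking, fell by 5.19, and B4GAT1, a glycosyltransferase that modifies dystroglycan, fell by 5.13. KIAA0101, which encodes the PCNA-binding factor PCLAF, fell from 733 ± 16.2 to 19.6 ± 1.18 CPM (log2 fold change −4.99, SE 0.08, edgeR adjusted p = 8.31e-14). ATG16L2, a homologue of the autophagy factor ATG16L1, fell by 5.08 from 22.7 ± 3.67 CPM, with a log2 fold change of −5.75 without depleted replicate 1. The exons of ATG16L2 overlap those of FCHSD2 on the other strand. Scaling by library totals alone in place of trimmed-mean factors moved the median gene by −0.23 on the log2 scale and gave 4132 higher and 5925 lower genes, so each log2 fold change in the text is relative to the trimmed-mean scaling, whereas CPM values and the ratios and lower bound from counts use library totals.

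**Figure D1:**
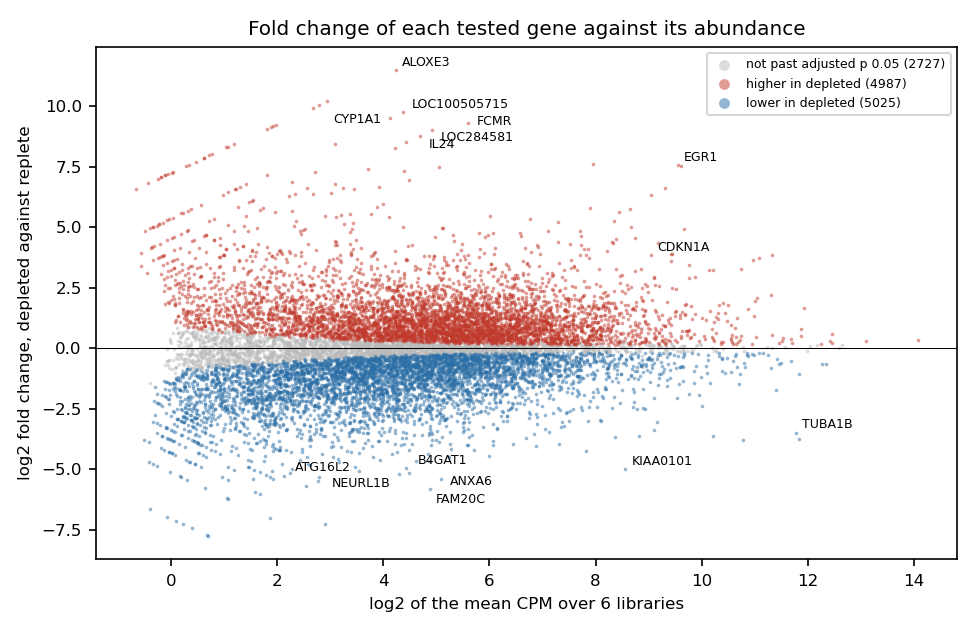
Each point is 1 of 12739 tested genes, at its log2 fold change (depleted against replete, vertical axis) and the log2 of its mean CPM over the 6 libraries (horizontal axis), with the 4987 genes higher in depleted cells in red, the 5025 lower in blue and those that did not pass an edgeR adjusted p of 0.05 in grey. Changes in both directions occur at every abundance, and the slanted rows of points at the left are genes with very few counts in 1 group, whose fitted fold change depends on the prior count.

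The second question was how the genes of the amino acid response behaved. Many of the best-known stress-induced targets of the transcription factor ATF4 rose, while others fell. PPP1R15A, the GADD34 subunit that directs dephosphorylation of eIF2α, rose from 16.8 ± 0.698 to 787 ± 40.8 CPM (n = 3 per group, log2 fold change 5.78, edgeR adjusted p = 4.84e-14). DDIT3, which encodes the stress transcription factor CHOP, rose from 121 ± 3.14 to 1247 ± 19.5 CPM (log2 fold change 3.60, edgeR adjusted p = 1.84e-13), with exons that overlap those of MARS on the other strand, so the genes may have shared counts. The secreted stress factor GDF15 rose by 3.46 on the log2 scale, and TRIB3, a pseudokinase that feeds back on ATF4 and CHOP, rose by 2.54. ASNS, asparagine synthetase, which uses glutamine as its nitrogen donor, rose by only 0.80, from 371 ± 2.47 to 552 ± 32.3 CPM (edgeR adjusted p = 9.76e-08). CHAC1, a glutathione-degrading enzyme often used as an ATF4 readout, had a log2 fold change of −0.04 (edgeR adjusted p = 0.844) at 14.7 ± 1.90 CPM in replete and 12.3 ± 2.75 CPM in depleted cells. JDP2, a repressor of the AP-1 family, fell by 3.13, DDIT4, an inhibitor of mTORC1 signalling, fell from 453 ± 6.24 to 129.8 ± 15.6 CPM, and EIF4EBP1, a translation repressor, fell by 1.78. Over the list, 16 of 27 tested members rose, 9 fell and 2 did not pass, with the same counts adjusted over the list alone. The list had a median log2 fold change of 1.22 and did not pass as a set, with a camera adjusted p of 0.0652. It passed without replete replicate 2 (camera adjusted p = 0.0492) and in 5 of the other alternatives, over which its adjusted p ran from 7.34e-07 to 0.323.

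Enzymes of glutamine and glutamate metabolism also moved in both directions, but more of them fell than rose. The cytosolic aspartate aminotransferase GOT1 rose by 2.45 on the log2 scale. IDH1, the cytosolic NADP-dependent isocitrate dehydrogenase, fell from 455 ± 20.6 to 99.7 ± 7.81 CPM (log2 fold change −1.96), glutamate dehydrogenase GLUD1 fell by 1.51, and the mitochondrial aminotransferase GOT2 fell by 0.98. GLUL, glutamine synthetase, fell from 24.2 ± 1.35 to 13.0 ± 1.51 CPM (log2 fold change −0.66, edgeR adjusted p = 0.000402). Over this list, 6 of 21 tested members rose and 14 fell, as they did adjusted over the list alone, and the set had a camera adjusted p of 0.112. Of 17 amino acid transporters, 9 rose and 5 fell, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.323). SLC3A2, the heavy chain shared by several heteromeric transporters, rose from 159.6 ± 4.26 to 777 ± 49.8 CPM, the lysosomal exporter SLC36A1 rose by 2.49 and the cationic amino acid importer SLC7A1 by 1.52. SLC1A5, a main glutamine importer, fell by 0.45 (edgeR adjusted p = 0.000134). After a trend over transcript GC content and length was removed, its log2 fold change was −0.13 with an adjusted p of 0.104, the highest over its alternatives, which went down to 2.13e-09. SLC7A11, the cystine–glutamate antiporter, had a log2 fold change of 0.14 (edgeR adjusted p = 0.197) at 604 ± 36.1 CPM in replete and 567 ± 83.6 CPM in depleted cells, and passed without depleted replicate 2, at 0.25 (adjusted p = 4.29e-05, with 4.29e-05 to 0.738 over its alternatives).

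Among the cytosolic aminoacyl-tRNA synthetases and the exporter XPOT, 14 of 21 rose and 4 fell, with the same counts adjusted over the list alone (median log2 fold change 0.48, camera adjusted p = 0.0706). CARS, the cysteine enzyme, rose from 83.0 ± 0.941 to 290.4 ± 42.7 CPM and YARS, the tyrosine enzyme, rose by 1.65. MARS, the methionine enzyme, had the smallest p of the list at a log2 fold change of 2.47, but its exons overlap those of DDIT3 on the other strand, so the counts of either gene may include reads of the other. Exons of YARS, MTHFD2, SLC7A11, ENO1 and SLC2A1 also overlap a counted gene on the other strand. QARS, which charges tRNA with glutamine, fell from 56.3 ± 1.80 to 15.3 ± 1.98 CPM (log2 fold change −1.66, edgeR adjusted p = 2.22e-08), and the lysine and phenylalanine enzymes KARS and FARSA fell by 0.64 and 0.90. Of 12 serine, glycine and one-carbon enzymes, 3 rose and 8 fell, or 3 and 9 adjusted over the list alone (median −0.66, camera adjusted p = 0.0887). PSAT1, the aminotransferase of serine synthesis that takes nitrogen from glutamate, fell from 448 ± 11.03 to 71.0 ± 3.97 CPM (log2 fold change −2.43, edgeR adjusted p = 1.07e-11), and the mitochondrial folate enzyme MTHFD2 fell by 0.73.

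**Figure D2:**
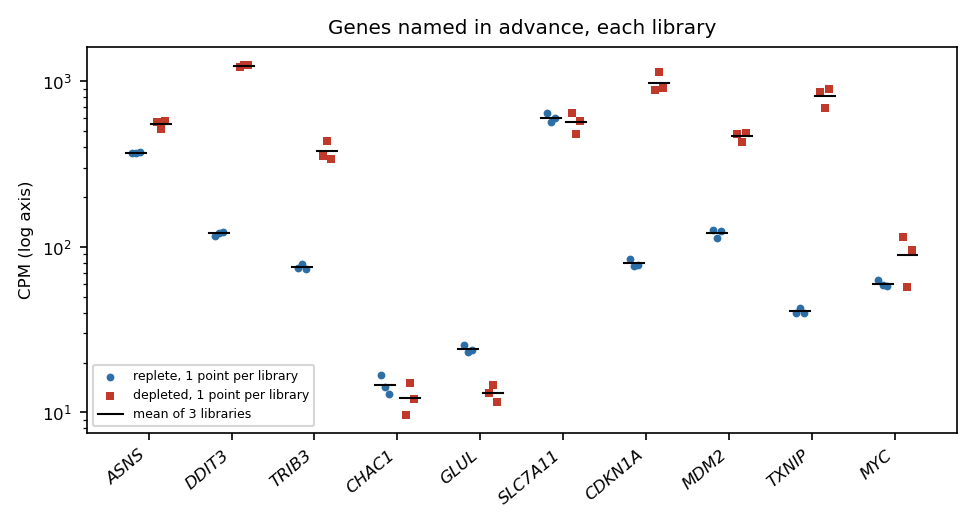
CPM of 10 genes named in advance (log axis), with 1 point per library, circles for replete and squares for depleted cells, and a line at the mean of 3 libraries. DDIT3, TRIB3, CDKN1A, MDM2 and TXNIP lie far apart between the groups, whereas CHAC1 (edgeR adjusted p = 0.844) and SLC7A11 (0.197) overlap, and the depleted MYC points spread from near the replete level upwards.

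The growth regulator genes named in this paragraph all rose, except CCNG1. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 79.5 ± 3.94 to 981 ± 134 CPM (n = 3 per group, log2 fold change 3.85, edgeR adjusted p = 6.76e-12), and MDM2, which encodes a ubiquitin ligase, rose from 122 ± 7.38 to 466 ± 28.9 CPM (2.16). AEN, an apoptosis-enhancing nuclease, rose by 3.91 to 1280.5 ± 47.1 CPM, and PHLDA3, an inhibitor of AKT signalling, rose from 90.1 ± 5.63 to 616 ± 38.3 CPM. The cyclin gene CCNG1 fell from 64.3 ± 3.98 to 35.3 ± 3.97 CPM (log2 fold change −0.64, edgeR adjusted p = 8.00e-05).

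Genes of DNA replication and mitosis fell. CDT1, which licenses replication origins, fell from 56.7 ± 2.46 to 3.47 ± 0.855 CPM (log2 fold change −3.78, edgeR adjusted p = 1.50e-10), the replicative helicase subunit MCM4 fell by 2.19 and the helicase loader CDC6 by 2.59. None of 36 replication and S-phase genes rose and 32 fell (median −1.27, camera adjusted p = 2.07e-06, and adjusted p = 0.0541 with an estimated correlation), while 1 rose after the GC and length trend was removed. For mitosis, PTTG1, the securin that guards sister chromatids, fell from 538 ± 9.16 to 113 ± 0.587 CPM, the mitotic kinase AURKB fell by 2.63, and the kinetochore component NUF2 fell by 2.59. The kinase-associated proteins CKS2 and CKS1B went the other way, CKS2 from 65.6 ± 2.71 to 119 ± 3.33 CPM and CKS1B from 938 ± 38.7 to 1396 ± 14.5 CPM. Of 38 G2 and mitosis genes, 5 rose and 31 fell (median −1.14, camera adjusted p = 1.93e-05, and adjusted p = 0.0717 with an estimated correlation), and with library totals alone 2 rose. Among 23 nucleotide synthesis genes, 20 fell and 1 rose (median −0.97, camera adjusted p = 0.000324, and adjusted p = 0.0960 with an estimated correlation). PRPS2, which makes the ribose donor PRPP, fell from 58.1 ± 0.723 to 8.07 ± 1.65 CPM, IMPDH1, of guanine nucleotide synthesis, fell by 2.13, and ADSL, of purine synthesis, fell by 1.85. The member that rose was CTPS1, the glutamine-using CTP synthase, from 125 ± 4.73 to 146 ± 13.4 CPM (log2 fold change 0.45, edgeR adjusted p = 0.000281). Counts adjusted over the list alone were the same for the replication, mitosis and nucleotide lists.

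Of the 16 replication-dependent histone genes listed, 8 could be tested and 6 of these rose, also adjusted over the list alone (median 1.39, camera adjusted p = 0.0177, and adjusted p = 0.233 with an estimated correlation). With cameraPR, which takes a precomputed statistic per gene, the set had an adjusted p of 0.0850, within a range of 0.000178 to 0.233 over its alternatives. The linker histone gene HIST1H1C rose from 31.3 ± 3.59 to 98.3 ± 2.85 CPM, and HIST1H4C rose from 57.2 ± 9.55 to 263 ± 53.5 CPM. These genes have near-identical copies, and most of their transcripts end in a stem-loop in place of a poly(A) tail, so their counts are uncertain and describe polyadenylated transcripts.

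Immediate early genes showed some of the steepest increases. EGR1, a zinc-finger transcription factor induced by growth factors and stress, rose from 9.02 ± 0.178 to 1491 ± 92.1 CPM (n = 3 per group, log2 fold change 7.59, edgeR adjusted p = 9.69e-15), the smallest p of all genes tested. The AP-1 subunit JUN rose from 14.98 ± 1.42 to 1041 ± 49.8 CPM (6.34) and IER2, a nuclear immediate early protein, from 366 ± 10.6 to 3076 ± 257 CPM (3.30). The ERK phosphatase gene DUSP4 and the ETS factor genes ETV5 and ETV4, which follow ERK activity, fell by 0.89, 0.96 and 0.82. Of 25 members, 20 rose and 4 fell, as they did adjusted over the list alone (median 1.92, camera adjusted p = 0.000251, and adjusted p = 0.0960 with an estimated correlation). MYC, the growth-promoting transcription factor, rose by 0.80 (edgeR adjusted p = 0.0193) from 59.9 ± 2.96 to 89.2 ± 29.01 CPM, with wide spread between depleted libraries. It did not pass without depleted replicate 3 (adjusted p = 0.0527), replete replicate 1 (0.0543) or replete replicate 2 (0.0622), nor with library totals alone (0.0743) or no count filter (0.0851), and its adjusted p ran down to 6.92e-15 over the alternatives.

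Of 15 targets of YAP and TEAD, the effectors of the Hippo pathway, 14 rose and 1 fell (median 1.99, camera adjusted p = 9.77e-05, and adjusted p = 0.154 with an estimated correlation). ANKRD1, a transcriptional cofactor, rose from 14.9 ± 1.67 to 1259 ± 84.7 CPM (log2 fold change 6.62, edgeR adjusted p = 4.84e-14). The Hippo kinase LATS2 rose by 3.37 and the LATS-binding scaffold AJUBA by 3.86, whereas NT5E, the ecto-nucleotidase CD73, fell by 0.95. Of 21 NF-κB and inflammatory cytokine genes, 16 rose and 1 fell (median 2.39, camera adjusted p = 0.000237, and adjusted p = 0.165 with an estimated correlation). With library totals alone, 2 of these genes fell. The NF-κB subunit RELB rose from 19.2 ± 2.04 to 405 ± 58.3 CPM, the subunit NFKB1 rose by 3.05, and the chemokine CXCL3 rose from 12.5 ± 0.293 to 190.6 ± 26.2 CPM. TNFAIP2, a TNF-inducible gene, fell from 994 ± 16.4 to 359.6 ± 64.8 CPM. Interferon-responsive genes did not pass as a set (camera adjusted p = 0.181), with 7 of 23 higher and 14 lower. Counts adjusted over the list alone were the same for these 3 lists.

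Lipid synthesis genes fell. FASN, fatty acid synthase, fell from 486 ± 11.4 to 54.2 ± 3.46 CPM (n = 3 per group, log2 fold change −2.94, edgeR adjusted p = 4.06e-12), the desaturase SCD fell by 2.05 and ACLY, which makes cytosolic acetyl-CoA from citrate, fell by 1.78. Of 17 fatty acid synthesis genes, 13 fell and 1, the elongase ELOVL1, rose (median −1.10, camera adjusted p = 0.00115, and adjusted p = 0.0960 with an estimated correlation). Of 24 genes of cholesterol synthesis and uptake, 18 fell and 3 rose (median −0.79, camera adjusted p = 0.00528, and adjusted p = 0.154 with an estimated correlation). Squalene synthase FDFT1 fell from 147 ± 2.98 to 22.6 ± 0.916 CPM, and INSIG1, which retains the SREBP complex in the endoplasmic reticulum, fell by 2.67. HMGCS1, the HMG-CoA synthase at the entry of the pathway, rose from 142 ± 8.71 to 321 ± 21.8 CPM (log2 fold change 1.41, edgeR adjusted p = 2.23e-09).

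Most of the tested glycolysis genes fell. The glucose transporters SLC2A3 and SLC2A1 fell by 1.16 and 1.17, and hexokinase HK2 fell from 48.8 ± 1.45 to 12.2 ± 1.68 CPM, while the enolase ENO1 rose from 2738 ± 50.8 to 3169 ± 328 CPM (log2 fold change 0.44). Of 23 members, 17 fell and 4 rose (median −0.66, camera adjusted p = 0.0177, and adjusted p = 0.499 with an estimated correlation). Among 25 targets of NRF2, the antioxidant transcription factor that KEAP1 restrains, 18 fell and 3 rose, or 1 with library totals alone (median −0.60, camera adjusted p = 0.00309, and adjusted p = 0.154 with an estimated correlation). The aldo-keto reductase AKR1C1 fell from 843 ± 19.4 to 58.2 ± 1.42 CPM and AKR1C2 fell by 2.51, although these paralogs can share reads. The aldehyde dehydrogenase ALDH3A1 fell from 752 ± 18.8 to 203 ± 10.2 CPM, and HMOX1, heme oxygenase, rose from 18.4 ± 1.79 to 82.8 ± 10.6 CPM (log2 fold change 2.40, edgeR adjusted p = 1.22e-09). Counts adjusted over the list alone were the same for the lipid, glycolysis and NRF2 lists.

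Of 15 cytosolic heat shock and co-chaperone genes, 10 fell and 4 rose, also adjusted over the list alone (median −1.08, camera adjusted p = 0.0475, and adjusted p = 0.233 with an estimated correlation). The constitutive chaperone HSPA8 fell from 432 ± 16.9 to 19.7 ± 0.916 CPM (n = 3 per group, log2 fold change −4.23, edgeR adjusted p = 2.83e-13), and HSP90AA1 fell from 4275 ± 113 to 1097 ± 57.8 CPM. HSPA1A fell by 2.65 and has a near-identical copy, HSPA1B. HSPA4 and CHORDC1, which assist HSP70 and HSP90, rose by 1.11 and 1.46. This set did not pass without depleted replicate 1 (camera adjusted p = 0.0590), depleted replicate 2 (0.0614) or replete replicate 1 (0.0505), with library totals alone (0.0738), upper quartile factors (0.0692), a replicate block (0.0696) or a mean CPM of at least 10 (0.0586), over a range of 1.83e-06 to 0.233 for all its alternatives.

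Autophagy and lysosome genes rose. MAP1LC3B, which encodes the autophagosome marker LC3B, rose from 101 ± 0.254 to 827 ± 11.5 CPM (n = 3 per group, log2 fold change 3.26, edgeR adjusted p = 3.96e-13), its relative GABARAPL1 rose by 3.03, and FLCN, folliculin, which acts on RagC and RagD at the lysosome, rose from 35.3 ± 4.54 to 612 ± 35.2 CPM (4.34). Of 36 members, 27 rose and 4 fell, as they did adjusted over the list alone (median 0.84, camera adjusted p = 0.000161, and adjusted p = 0.0717 with an estimated correlation). The phosphoinositide-binding proteins WIPI2 and WIPI1 and the protease gene CTSB fell by 1.26, 1.54 and 0.42. WIPI1 exons overlap ARSG on the other strand. TXNIP, the glucose-responsive inhibitor of glucose uptake that MondoA induces, rose from 40.8 ± 1.85 to 819 ± 113 CPM (log2 fold change 4.55, edgeR adjusted p = 1.27e-12). Over the small MondoA and ChREBP list, 4 of 7 members rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.323).

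Several lists did not pass as sets with camera, which asks whether a list moved more than the other genes. With fry, which tests each list by itself, the lists of this paragraph passed (adjusted p from 4.92e-05 to 0.0450), except 2. These were the ribosomal protein list (0.319) and the ribosome biogenesis list (0.0856). Of 60 ribosomal protein genes, 20 rose and 15 fell (camera adjusted p = 0.817), but 5 rose and 26 fell with library totals alone. Of 45 nuclear genes of oxidative phosphorylation, 12 rose and 20 fell, or 12 and 19 adjusted over the list alone (camera adjusted p = 0.456), and with library totals alone 7 rose. After the GC and length trend was removed, 37 of these genes could be tested, of which 14 rose and 13 fell. Their median log2 fold change was then 0.06, against −0.07 for the list in the main fit. Of 23 genes of the tricarboxylic acid cycle, 3 rose and 10 fell (camera adjusted p = 0.127), and with library totals alone 1 rose and 17 fell, with an adjusted p of 0.0439 (4.92e-05 to 0.236 over its alternatives). Endoplasmic reticulum chaperone and unfolded protein response genes were split, 6 higher and 9 lower of 19 (camera adjusted p = 0.323), or 2 higher with library totals alone. Ribosome biogenesis and MYC-responsive genes were split 11 to 10 of 29 (0.965), with 7 higher and a median log2 fold change of −0.04 without replete replicate 2, and medians of −0.01 without depleted replicate 2 and −0.02 without replete replicate 3. Hypoxia-responsive genes were split 7 to 7 of 15 (0.965), polyamine genes 5 to 3 of 10 (0.771), and epithelial and mesenchymal genes 6 to 5 of 16 (0.817). The median and mean log2 fold changes differed in sign for the ribosomal protein list (0.08 and −0.02), the ribosome biogenesis list (0.03 and −0.01), the polyamine list (0.28 and −0.15) and the hypoxia list (−0.10 and 0.05, with a median of 0.01 without depleted replicate 2). With library totals alone, the medians of the ribosomal protein, ribosome biogenesis and epithelial lists were −0.15, −0.20 and −0.01.

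Markers of other cell types gave few counts. Of the fibroblast markers, COL3A1 rose from 11.4 ± 1.20 to 26.5 ± 3.90 CPM and PDGFRB rose by 1.60, whereas LUM fell from 10.3 ± 0.787 to 4.39 ± 0.378 CPM. Depleted replicate 3 stood apart in several of these markers, with COL1A1 at 56.5 CPM against 3.43 to 13.4 CPM in the other libraries, COL1A2 at 18.2 against 0.183 to 3.31 CPM and POSTN at 5.65 against 0.554 to 2.90 CPM. The set of 6 tested fibroblast markers had a camera adjusted p of 0.602, with 2 higher and 1 lower, and its median log2 fold change was 1.52, or −0.53 with 2 lower without depleted replicate 3. Of the 12 blood cell markers, 2 passed the count filter, and both fell, CD14, a monocyte receptor, from 2.60 ± 1.15 to 0.497 ± 0.0652 CPM and CD68, a lysosomal macrophage marker, from 7.15 ± 0.940 to 4.41 ± 0.748 CPM (edgeR adjusted p = 0.000874 and 0.0488). Mitochondrially encoded genes were not analysed here.

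**Figure D3:**
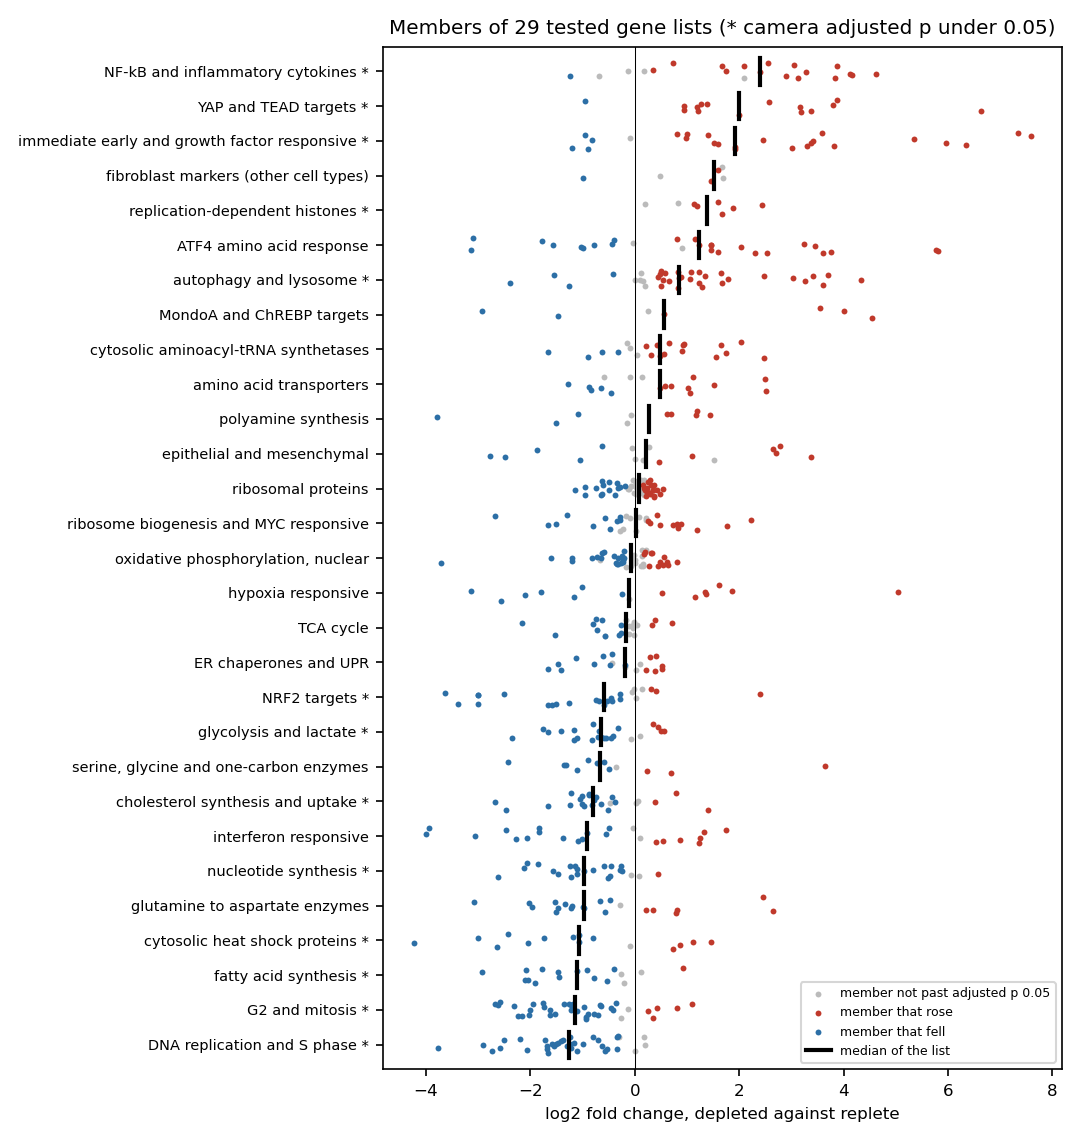
Log2 fold changes (depleted against replete, horizontal axis) of the tested members of 29 gene lists, 1 point per gene, red where it rose, blue where it fell and grey where the edgeR adjusted p did not pass 0.05, with a bar at each list's median and a star where camera's adjusted p passed. The starred lists run from NF-κB genes (median 2.39) and YAP and TEAD targets (1.99) to DNA replication genes (−1.27), and none of these lists passed with an estimated correlation.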

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

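The groups, comparison, gene lists and the alternatives were fixed before the data were examined, except the largest entry per symbol and the GC and length trend, which were chosen after seeing the data. Over all alternatives other than glmTreat, between 6956 (mean CPM of at least 10, where fewer genes were tested) and 11028 (no count filter) genes passed, and none of the calls turned the other way. Leaving out 1 library gave 9558 to 10625 genes. With glmTreat against 1.5-fold, which asks for a larger change by construction, 6779 genes passed, 3324 higher and 3455 lower. Camera called 14 lists. With an estimated correlation it called 0 lists (lowest adjusted p 0.0541), and with fry, which tests each list by itself without comparing it with other genes, it was 27. A higher correlation does not account for every lost call, because the estimate was below the preset 0.01 in some called lists. It was −0.00161 for DNA replication, −9.75e-05 for autophagy and lysosome, and −0.0150 for fatty acid synthesis. In other called lists it was higher, up to 0.372 for glycolysis. What else moved these calls was not tested. For single lists, 405 comparisons with an alternative kept their side, 22 lost and 21 gained a call. For named genes these were 1855, 26 and 2, and no result reversed. Library totals alone and upper quartile factors moved the median gene by −0.23 and −0.21. With upper quartile factors 4188 genes were higher and 5866 lower, 3 mitosis genes, 1 NRF2 target, 2 unfolded protein response genes and 5 ribosomal protein genes rose, and with library totals alone 1 NRF2 target and 7 ribosome biogenesis genes rose and 5 polyamine genes fell. Among genes named by the rule, MTHFD1L (log2 fold change 0.23, edgeR adjusted p = 0.0461) did not pass in several alternatives. Its adjusted p was 0.219 without replete replicate 1 and 0.150 without replete replicate 3, and ran from 0.00876 to 0.992 over all its alternatives. A block on the replicate number gave 9940 genes. The deviations of equally numbered libraries correlated across genes, which are not independent replicates, at 0.119, 0.00611 and 0.0366. Replicate 2 was closer to another number (0.0458), while for replicates 1 and 3 the highest correlation with another number was lower (−0.0280 and 0.0230). The numbers were not taken as pairs because the labels do not say that they mark a shared day.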

Other observations

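The families in the next paragraph and all tests on 3′ UTR elements across genes were chosen only after the result was seen.

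Of 14 tested tubulin genes, whose products build microtubules, 13 fell and none rose (median log2 fold change −2.06, camera p = 2.72e-05, and p = 0.0112 with an estimated correlation). TUBA1B fell from 6478 ± 135 to 497 ± 12.7 CPM (n = 3 per group, log2 fold change −3.48, edgeR adjusted p = 9.26e-14). TUBB6 had a log2 fold change of 0.19 (edgeR adjusted p = 0.0963), and 1 tubulin rose without depleted replicate 1. Tubulin paralogs can share reads. Of 19 subunits of the V-ATPase, the proton pump that acidifies lysosomes, 14 rose and 4 fell (median 1.21, camera p = 0.00158, and p = 0.0265 with an estimated correlation). ATP6V1C1 rose from 19.8 ± 1.16 to 122.7 ± 8.10 CPM and ATP6V0C from 655 ± 2.29 to 1631 ± 210 CPM, while ATP6V0E2 fell by 1.31 on the log2 scale. Of 367 zinc finger genes with a ZNF symbol, 240 rose and 62 fell (median 1.10, camera p = 1.39e-07, and p = 0.000356 with an estimated correlation), and 216 rose and 73 fell with library totals alone. The 3 families lay at percentiles 0, 99.85 and 100 of 10000 random gene lists of matched abundance. Neither these percentiles nor the p-values are adjusted for the choice of families from the same data, and the random lists did not group related genes.

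The breadth of the change, 10012 genes, was set against technical explanations. The real split of the 6 libraries was 1 of 10 splits with a count as large, the highest other split gave 0 genes, and 10 splits are too few for a share under 0.05. After a trend over GC content and transcript length was removed, 93.9% of the calls with transcript features were kept, and 98.3% of all calls were kept without depleted replicate 2, which argues against either as the whole cause. A difference in culture or handling that goes with the groups could not be separated from the lack of glutamine, which remains a possible explanation.

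Within the ATF4 list, members moved in both directions, 16 up and 9 down. Of the 25 called members, 24 were kept after the GC and length trend was removed, and at least 25 were kept in each fit without 1 library, so neither accounts for the split. Members that rose held 0.03 more UAUUUAU elements per 3′ UTR than members that fell (permutation p = 1, 2-sided), which decides nothing with so few genes. No other biological explanation was tested.

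Genes with UAUUUAU elements, a sequence bound by proteins that destabilise mRNA, tended to lie higher in depleted cells. The median log2 fold change was −0.12 for 6889 genes without one, 0.08 for 2320 with 1, 0.30 for 959 with 2 and 0.32 for 823 with 3 or more. Genes with an element lay 0.284 higher on average over the 10991 genes with a 3′ UTR long enough to search. They lay 0.184 higher within 25 strata of 3′ UTR GC content and length, which removed part of the difference. Within 20 strata of abundance they lay 0.284 higher, which argues against abundance as the whole cause. Each difference had a permutation p of 1e-05, the smallest that 100000 permutations can give. GC content and length still varied within a stratum, so this test cannot exclude them as the whole cause. Within the same strata of 3′ UTR GC content and length, and with the same limit, genes with 3 or more lay 0.249 above genes with 1 (permutation p = 0.00043). Slower decay of such mRNAs may contribute, as a hypothesis found and tested on the same data, in which genes are not independent replicates.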
